A study of Mus musculus with 6 samples.

How the data were processed

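RNA sequencing had been done on upper-layer neurons of the cerebral cortex of Swiss Webster mice at postnatal day 3 (P3) and postnatal day 5 (P5). Per the labels, the neurons carried green fluorescent protein (GFP) and were isolated by fluorescence-activated cell sorting, total RNA was extracted with a column kit, and libraries were prepared by the standard protocol of the sequencer's maker. The 6 samples comprised 3 biological replicates at P3 and 3 at P5, grouped by the age in their titles. The submitters' processing notes list TopHat, Cuffdiff 2.02 and the mouse genome build mm9, without the role or order of each step. The gene annotation, the read length, the strandedness of the libraries and the number of reads are not given in the sources used here.

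A single table was analysed, which compares the ages gene by gene. Expression is deposited in it as FPKM (fragments scaled to transcript length and to the total of fragments), with 1 value per age that Cuffdiff pooled from the replicates, per the file headers. It also holds the log2 ratio of P5 over P3, a test statistic, a p-value and a q-value for each gene, all made by the authors. The log2 ratio and the test statistic were handled as scores, because the deposited log2 column holds a placeholder where 1 age is listed at 0. No value per replicate was used here, and no column of per-sample values was left aside. The spread between replicates could therefore be read only through the deposited test. Since FPKM keeps no count of fragments, the depth of each library is unknown. Cuffdiff gave each of the 22544 rows a status, which was OK (tested) in 12865, NOTEST in 9496, LOWDATA in 143, FAIL in 37 and HIDATA in 3.

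The main test was the authors' own Cuffdiff test at q = 0.05, taken for rows with status OK, since a new test across replicates cannot be made from pooled values. In the 12313 tested rows with FPKM above 0 at both ages, the deposited p-value equalled the two-sided normal tail of the test statistic to within 2.8e-06, and the statistic had the opposite sign to the log2 ratio. A standard error of each log2 ratio was therefore taken as the size of the ratio divided by the statistic, and 95% intervals as 1.96 standard errors either side. An FPKM of exactly 0 can be a failed estimate in such a table. Of 58 ribosomal protein genes looked up, 3 were listed at 0 at both ages and only 33 had been tested, so a gene at 0 is described only as listed at 0 and is given no fold.

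Gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The 31 lists hold 837 genes of the table, 16 of them in more than 1 list, and cover the cell cycle, DNA damage and cell death, neuronal maturation, markers of other cell types, and quality checks. For each list the members with a significant result were counted, the deposited p-values were adjusted by the Benjamini-Hochberg method over the list alone, and the median log2 ratio was set among the medians of 10000 random lists of the same size. Random lists were drawn without repeats from the 12313 rows, matched on deciles of mean FPKM. A list was said to stand apart when its median lay outside the central 95% of the random medians. That position describes this table and is not a p-value, because genes are not replicates.

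The rule named 20 cell cycle and neuronal genes whatever their values, the significant genes with the largest ratios, and, for a list without a significant member, its 2 members with the highest mean FPKM. Because no gene passed the test, further genes were named after their values were seen. These were the 10 with the lowest p in each direction, the 4 members with the lowest p in the direction of each list that stood apart, and the 2 with the lowest p in each other list, all with FPKM of at least 5 at either age. Clones, predicted genes, small RNAs and rows naming several genes were left out of the 10 in each direction. Symbol families in the closing section, each with at least 12 tested members, were chosen after the values were seen as well. Some of the genes that these rules name are not reported here.

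Loci are given on mm9 as in the deposited table. Their start positions were read as counted from 0 and are printed counted from 1. Among 17037 genes also present in GENCODE M21, the difference of end and start equalled the annotated gene length in 2565 and was 1 short of it in 424. No coordinate of the newer build was used. Some deposited loci span several genes. In all, 3710 rows share their locus with another row, and without strand information reads of overlapping genes cannot be told apart.

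Alternatives fixed with them were q at 0.01, a minimum log2 ratio of 1, a minimum of 1 FPKM at either age, no filter on low values, log2 ratios centred on their median, Bonferroni adjustment, leaving out markers of other cell types, pseudocounts of 1 and 0.1 FPKM, means in place of medians, and random lists that were not matched. Dividing the test statistic by its robust spread over genes, matching random lists on P5 FPKM, and leaving out members below 0.1 FPKM at either age were added after seeing the data.

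The steps were tested on simulated data. Log2 ratios were drawn for the 12313 genes with the standard errors of the table, and 200 genes were changed by a known amount. With changes of 2 log2 units 0 of the 200 were recovered at q = 0.05, with 4 units 68 were recovered, and with 8 units 151. For lists, 30 genes drawn at random were shifted within the deposited ratios and set among fewer random lists than above. Shifted by 1 log2 unit they fell outside the central 95% in 200 of 200 draws, by 0.5 units in 93, and without a shift in 8. Genes drawn at random need not vary together, so these rates do not carry over to lists whose genes do. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.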

Results

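Gene expression was measured by RNA sequencing in GFP-labelled upper-layer cortical neurons sorted from mice at P3 and P5, with 3 biological replicates at each age. The design has 1 comparison, P5 against P3, within a series concerned with how young neurons come to leave the cell cycle for good. All expression values below are the FPKM of the authors' deposited table, which gives 1 pooled value per age, and every ratio is P5 over P3 on the log2 scale with the standard error (SE) implied by the test statistic of that table. FPKM reached 1 in 10226 rows at P3 and in 11273 rows at P5. Depth is unknown, because the table holds no counts.

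No gene differed between P3 and P5 at q = 0.05. Cuffdiff, run by the authors, called 0 genes higher and 0 genes lower at P5 among 12865 tested, and the lowest q in the authors' deposited table was 0.999988. At an unadjusted p under 0.05 there were 99 genes, 76 with higher FPKM at P5 and 23 with lower FPKM, against 643 that uniform p-values would give. Of the 9665 genes with FPKM of at least 1 at both ages, 78.5% had a log2 ratio between -1 and 1, and the median ratio was 0.02. The errors were wide beside these ratios, with a median SE of 1.38 log2 units and a lowest SE of 0.82. In simulated data with these errors, changes of 2 log2 units were recovered in 0 of 200 genes, so differences of that size were not detectable by this test. Across genes the test statistic had a robust spread of 0.66, below the 1 of a standard normal, and in the highest decile of FPKM the median SE of 0.98 exceeded the SD of the ratios themselves, 0.73, so the SEs and intervals given here are probably too wide.

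Cell cycle genes were the first group of interest. D-type cyclins drive entry into the cycle with Cdk4 and Cdk6. In the authors' deposited table Ccnd1 (mm9 chromosome 7, 152115836 to 152125830) had 54.5 FPKM at P3 and 32.5 at P5, a log2 ratio of -0.75 (SE 0.89), and Ccnd2 had 127 and 101 (-0.33, SE 1.30). Cdk4 was at 120 and 116 FPKM. The lowest p-values of the G1/S list in the authors' deposited table belonged to Skp2, a subunit of the ubiquitin ligase that degrades p27, at 19.3 and 5.33 FPKM (p = 0.11), and to the S-phase kinase Cdk2 at 9.36 and 2.34 (p = 0.18). Of 18 tested genes of the G1/S list, 7 had higher and 11 had lower FPKM at P5, and the list median of -0.20 lay within the central 95% of matched random lists (-0.35 to 0.77). With only members of at least 1 FPKM at either age, the median was -0.52 and lay below that of matched random lists (-0.40 to 0.71). As a mean, the value of the list was -0.05, within the random range (-0.30 to 1.14).

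The DNA replication list stood apart on the lower side. Its median log2 ratio was -0.25 over 44 tested genes, 27 of them with lower FPKM at P5, and 137 of 10000 matched random lists had a lower median. Uhrf1 (mm9 chromosome 17, 56442760 to 56462909), which keeps DNA methylation in place through replication, had 21.2 FPKM at P3 and 1.52 at P5 in the authors' deposited table (log2 ratio -3.80, SE 1.43, p = 0.0078). The histone chaperone subunit Chaf1a was at 6.92 and 1.63 FPKM, and the helicase subunits Mcm5 and Mcm2 were at 14.1 and 7.23 and at 12.9 and 9.74. Rfc4 and Rfc2, clamp loader subunits with the highest FPKM of the list, had 87.5 and 50.4 and 49.8 and 43.4 FPKM, while the clamp gene Pcna had 1.25 and 1.27. With the mean in place of the median, the value of this list was -0.04 and lay within the random range (-0.08 to 0.72).

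Genes of G2 and mitosis did not stand apart. In that list 25 of 47 tested genes had higher and 22 lower FPKM at P5, with a median of 0.01. The proliferation marker Mki67 (mm9 chromosome 7, 142881471 to 142908062) had 9.69 FPKM at P3 and 5.96 at P5 in the authors' deposited table (log2 ratio -0.70, SE 1.01). The mitotic kinase Cdk1 had 16.1 and 12.9, the topoisomerase Top2a 28.9 and 22.1, and Cdca8, part of the complex that corrects chromosome attachment, 58.5 and 35.2 FPKM. The 2 Aurora kinases with the lowest p-values of the list went in opposite directions, Aurkb with 1.59 and 10.2 FPKM and Aurka with 19.1 and 6.95.

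CDK inhibitors, RB family genes and other antiproliferative genes stood apart on the lower side as 1 list, by their ratios. Their median FPKM was not lower, at 9.35 at P3 and 10.5 at P5. The list of CDK inhibitors and RB family genes had a median of -0.39 over 18 tested genes, 11 with lower and 7 with higher FPKM, and 180 of 10000 matched random lists had a lower median. Cdkn1c (mm9 chromosome 7, 150644244 to 150646955), which encodes the inhibitor p57, had 67.3 FPKM at P3 and 20.8 at P5 in the authors' deposited table (log2 ratio -1.69, SE 0.94, p = 0.072). Cdkn1b, which encodes p27, was at 78.1 and 40.1 FPKM (mm9 chromosome 6, 134870419 to 134875543). Cdkn1a, which encodes p21, was at 4.65 and 9.17, and Cdkn2a was listed at 0 at both ages and was not tested. The antiproliferative genes Btg2 and Btg1 had 184 and 121 and 96.8 and 35.8 FPKM, Tob1 25.7 and 10.5, Gas1 74.95 and 27.0, and the atypical cyclin gene Ccng2 44.2 and 17.5. Tob1, Gas1 and Ccng2 were named for their low p in the direction of the list. Rb1 had 17.5 and 10.6 FPKM and Rbl2 7.19 and 7.13, at loci that each hold at least 1 other gene of the table.

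Tumour suppressors as a list stayed within the random range, with a median of -0.13 and 22 of 37 tested genes at lower FPKM at P5. Trp53 had 11.4 FPKM at P3 and 10.05 at P5. Ndrg2 and Tusc3, with the highest FPKM of the list, were at 111 and 122 and at 57.9 and 93.7, and Wwox was at 2.03 and 11.4. The plot of the genes named in advance shows how wide the errors were.

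**Figure D1:**
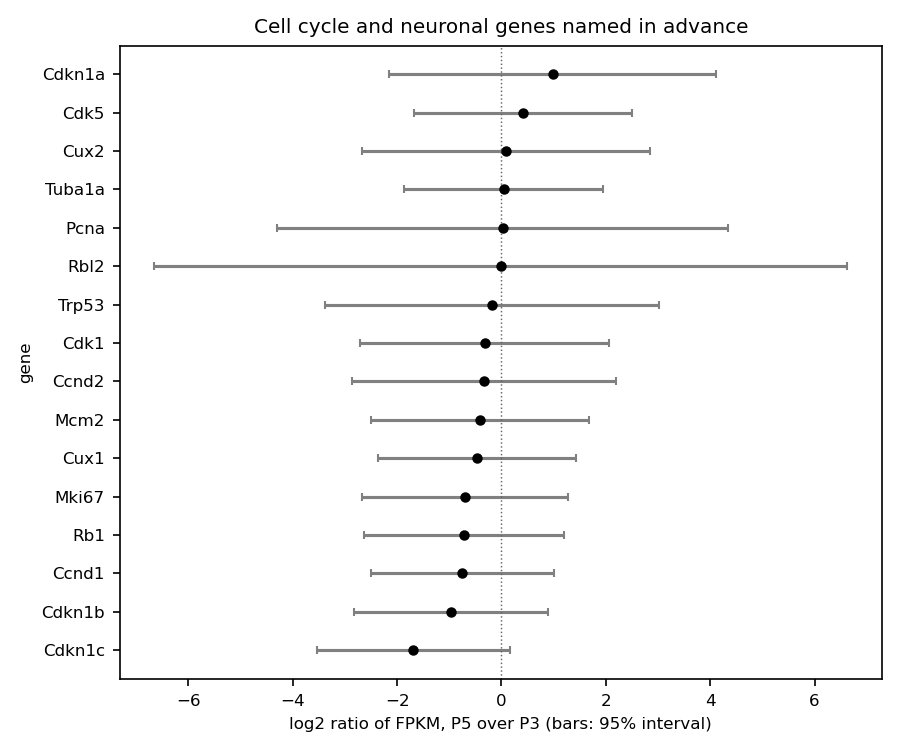
Log2 ratio of FPKM, P5 over P3, for 16 of the genes named in advance (points), with 95% intervals from the test statistic of the authors' deposited table (bars). Every interval reaches 0, but with SEs multiplied by 0.66, a scaling chosen after seeing the data, that of Cdkn1c does not (-2.92 to -0.47).

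Other genes tied to cell division and survival were examined in 3 further lists. The DNA damage response and repair list had a median of -0.41 over 30 tested genes, 21 with lower FPKM at P5, and 26 of 10000 matched random lists had a lower median. The end-joining factor Xrcc4 had 32.7 and 14.3 FPKM in the authors' deposited table, the checkpoint kinase Chek2 9.23 and 2.56, and the ligases Lig3 and Lig4 6.48 and 2.57 and 7.77 and 3.79. Of the most abundant repair genes, Apex1 (82.2 and 62.4 FPKM) had a log2 ratio of -0.40, close to the list median, and Ercc1 (41.2 and 40.4) one of -0.03. With the mean in place of the median, this list had a value of -0.06, within the random range. Targets of p53 had a median of 0.64 with 16 of 22 genes higher at P5, and apoptosis regulators 0.39 with 15 of 25 higher, both within the random range. With a pseudocount of 1 FPKM these medians were 0.41 and 0.17, and that of apoptosis regulators was 0.083 with members of at least 1 FPKM at either age. Bax, which belongs to both lists, was at 71.4 and 74.5 FPKM, and Xiap, an inhibitor of caspases, was at 15.3 and 6.42. Sesn1 and Phlda3, the p53 targets with the lowest p, had 5.61 and 16.5 and 1.94 and 6.14 FPKM.

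The presynaptic vesicle release list had a median log2 ratio of 0.92, above all 10000 matched random lists, and 27 of its 28 tested genes had higher FPKM at P5. The SNARE protein genes Stx1a and Snap25 had 2.93 FPKM at P3 and 35.4 at P5 (log2 ratio 3.59, SE 1.61) and 36.5 and 129 (1.82, SE 1.04) in the authors' deposited table. The vesicle protein Sv2a was at 7.48 and 23.3 FPKM and the calcium sensor Syt1 at 13.9 and 40.5. The most abundant member, Syt4 (782 and 1081 FPKM), had a ratio of 0.47. Stx1a had the lowest p of this list (p = 0.025 in the authors' deposited table), and adjusted over the list alone its q was 0.675.

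Receptor and channel lists had positive medians within the random range. The median was 0.45 for glutamate receptors and the postsynaptic density (22 of 31 genes higher at P5), 0.71 for sodium, potassium and HCN channels (20 of 29), 0.38 for calcium channels and calcium handling (20 of 30) and 0.52 for GABA receptors and chloride transporters (12 of 16). The sodium, potassium and HCN channels lay above the range with a pseudocount of 1 FPKM (0.66 against a high end of 0.62) and against lists that were not matched (0.71 against 0.65), and the GABA list did as a mean (0.88 against 0.84). The GABA receptor subunit Gabra4 had 6.89 FPKM at P3 and 14.9 at P5 in the authors' deposited table (log2 ratio 1.12, SE 1.04), and the more abundant Gabrb2 had 171 and 123. Among calcium genes, the sensor Hpca was at 3.31 and 56.3 FPKM, and the release channel Itpr1 at 8.17 and 2.27. The AMPA receptor subunit Gria2 was at 89.5 and 48.1 FPKM, the NMDA receptor subunit Grin2b at 111 and 114.5, and the potassium channel genes Kcnk2 and Kcnv1 at 22.5 and 22.3 and at 1.41 and 7.47.

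Axon guidance genes also stood apart on the lower side, with a median of -0.56, below all 10000 matched random lists, and 24 of 37 tested genes at lower FPKM at P5. With a pseudocount of 1 FPKM the median was -0.36, and the mean was -0.20. The receptor gene Robo1 (mm9 chromosome 16, 72663394 to 73046345) had 29.8 FPKM at P3 and 8.37 at P5 in the authors' deposited table (log2 ratio -1.83, SE 0.91, p = 0.043). The secreted cue Sema3c had 30.5 and 8.13 FPKM, the plexin Plxna2 21.8 and 10.6, and the adhesion molecule Cntn2 11.9 and 4.90. The ephrin genes with the highest FPKM of the list went in opposite directions, Efna5 at 38.0 and 81.5 and Efnb2 at 48.2 and 29.1. The immature neuron and migration list had a median of -0.25 with 16 of 29 genes lower, within the random range. It lay below that range as a mean (-0.28 against a low end of -0.24) and with random lists matched on P5 FPKM (-0.25 against -0.20). Its member Cxcr4, a chemokine receptor of migrating neurons, was at 37.2 and 6.42 FPKM. The microtubule genes Tuba1a (128 and 132 FPKM) and Dcx (73.0 and 51.0, with status FAIL and so not tested) were high at both ages, as was the growth cone gene Gap43 (1243 and 1474).

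Upper-layer identity genes, which the sorted neurons should carry, had a median of 0.06, with 9 of 16 higher and 7 lower at P5. This ratio does not show how pure the sorts were. Median FPKM of the tested members was 27.4 at P3 and 21.4 at P5, against 26.8 and 67.7 for astrocyte markers. Astrocyte transcripts were thus already present at P3. In the authors' deposited table the transcription factor gene Cux1 was at 34.9 FPKM at P3 and 25.3 at P5 (log2 ratio -0.47, SE 0.97), Cux2 at 1.87 and 1.99, Pou3f3 at 66.1 and 21.3, Mef2c at 156 and 226 and Rorb at 119 and 152. Markers of deep-layer and subplate neurons stood apart on the higher side, with a median of 1.18, 16 of 19 genes higher at P5, and 9995 of 10000 random lists below. Rprm had 5.43 and 51.4 FPKM, Pcp4 14.5 and 49.3, Syt6 2.62 and 7.45 and Cplx3 0.055 and 5.45, whereas the most abundant marker of the list, Nfia, had 356 and 233.

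Markers of microglia, vessels and oligodendrocytes lay further from 0 than any neuronal list, in the same sorts that gave the cell cycle, synapse and axon guidance values above. Microglia and macrophage markers had a median log2 ratio of 4.46 with 17 of 17 genes higher at P5, and endothelial and mural cell markers one of 2.73 with 15 of 17 higher. These sizes rest on low values at P3 (median 0.48 and 0.40 FPKM), and with a pseudocount of 1 FPKM the medians were 2.61 and 1.14. Oligodendrocyte lineage markers had a median of 1.59 (14 of 14 higher) and astrocyte markers 0.98 (16 of 18 higher). All of these 4 medians lay above all 10000 matched random lists. The microglial genes Fcer1g and Cd68 were at 0.49 and 30.4 FPKM and at 0.19 and 15.8 in the authors' deposited table, while C1qb, more abundant at P3, was at 9.69 and 27.5. Vtn, a pericyte gene, had 1.40 and 25.1 FPKM and the endothelial tight junction gene Cldn5 0.80 and 11.2, but Rgs5 had 911 and 905. The oligodendrocyte gene Ugt8a was at 1.12 and 9.76 FPKM and Olig1 at 48.1 and 50.9. Among astrocyte genes, Apoe was at 64.9 and 498 FPKM, Gfap at 17.2 and 79.8, Gja1 at 362 and 717 and Aldoc at 767 and 773. The 2 tested erythroid genes, Hbb-b2 (1.90 and 63.2 FPKM) and Alas2 (0.62 and 7.92), had a median ratio of 4.37.

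Progenitor and interneuron markers did not share this position. Radial glia and neural stem cell markers had a median of -0.36 with 15 of 21 genes lower at P5, and 209 of 10000 random lists had a lower median, although their mean of -0.20 lay within the random range. Fabp7 and Slc1a3, which radial glia share with astrocytes, reached 5388 and 4272 FPKM and 1088 and 758 FPKM. Emx2 was at 14.8 and 5.82 FPKM in the authors' deposited table. Intermediate progenitor markers had a median of -0.23 (6 of 10 lower), with Hes6 at 19.96 and 28.3 FPKM and Neurod1 at 14.3 and 5.17. That median was -0.11 with a pseudocount of 1 FPKM and -0.09 with members of at least 1 FPKM at either age, and the mean was -0.01. GABAergic interneuron markers had a median of -0.07 (8 of 15 lower), with Npy at 155 and 356 FPKM, Sst at 30.1 and 95.6 and Sp8 at 445 and 310.

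The remaining lists lay within the random range as reported. Oxidative phosphorylation had a median of 0.20 (32 of 49 genes higher at P5), but lay above it at 0.19 with members of at least 1 FPKM at either age (high end 0.17) and at 0.20 without members below 0.1 FPKM at either age (high end 0.196), with Cox4i1 at 472 and 679 FPKM and Uqcrq at 546 and 442. Cholesterol synthesis had a median of 0.30 (14 of 21 higher), with Nsdhl at 14.9 and 53.7 FPKM. Chromatin remodellers and histone modifiers had a median of -0.24 (20 of 31 lower), but lay below the range at -0.21 as a mean (low end -0.199) and at -0.24 with random lists matched on P5 FPKM (low end -0.22), with the DNA methyltransferase Dnmt3a at 105 and 55.4 FPKM and Smarca2 at 139 and 79.6. Immediate early and dissociation stress genes, a check on handling, had a median of 0.62 (14 of 18 higher), with Fos at 33.7 and 53.4 FPKM and the chaperone Hspa5 at 131 and 185. Cytosolic ribosomal proteins had a median of 0.21 over 31 genes. Of 58 listed, 24 reached 1 FPKM at P3 and 24 at P5. Median FPKM of the tested members was 5.33 at P3 and 4.04 at P5, far below the abundant Rpl8 at 202 and 310. The median ratio was 0.045 with members of at least 1 FPKM at either age, and the mean ratio was 0.098. Sex-linked check genes had a median of 0.65 over 5 genes, 4 higher and 1 lower at P5, so this median mixes opposite directions. In the authors' deposited table Xist was lower (6.78 and 3.22 FPKM), and the Y-linked Ddx3y (5.44 and 9.64) and Eif2s3y (9.71 and 12.7) were higher. They were present at each age, which does not show an equal mix of sexes at P3 and P5.

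**Figure D2:**
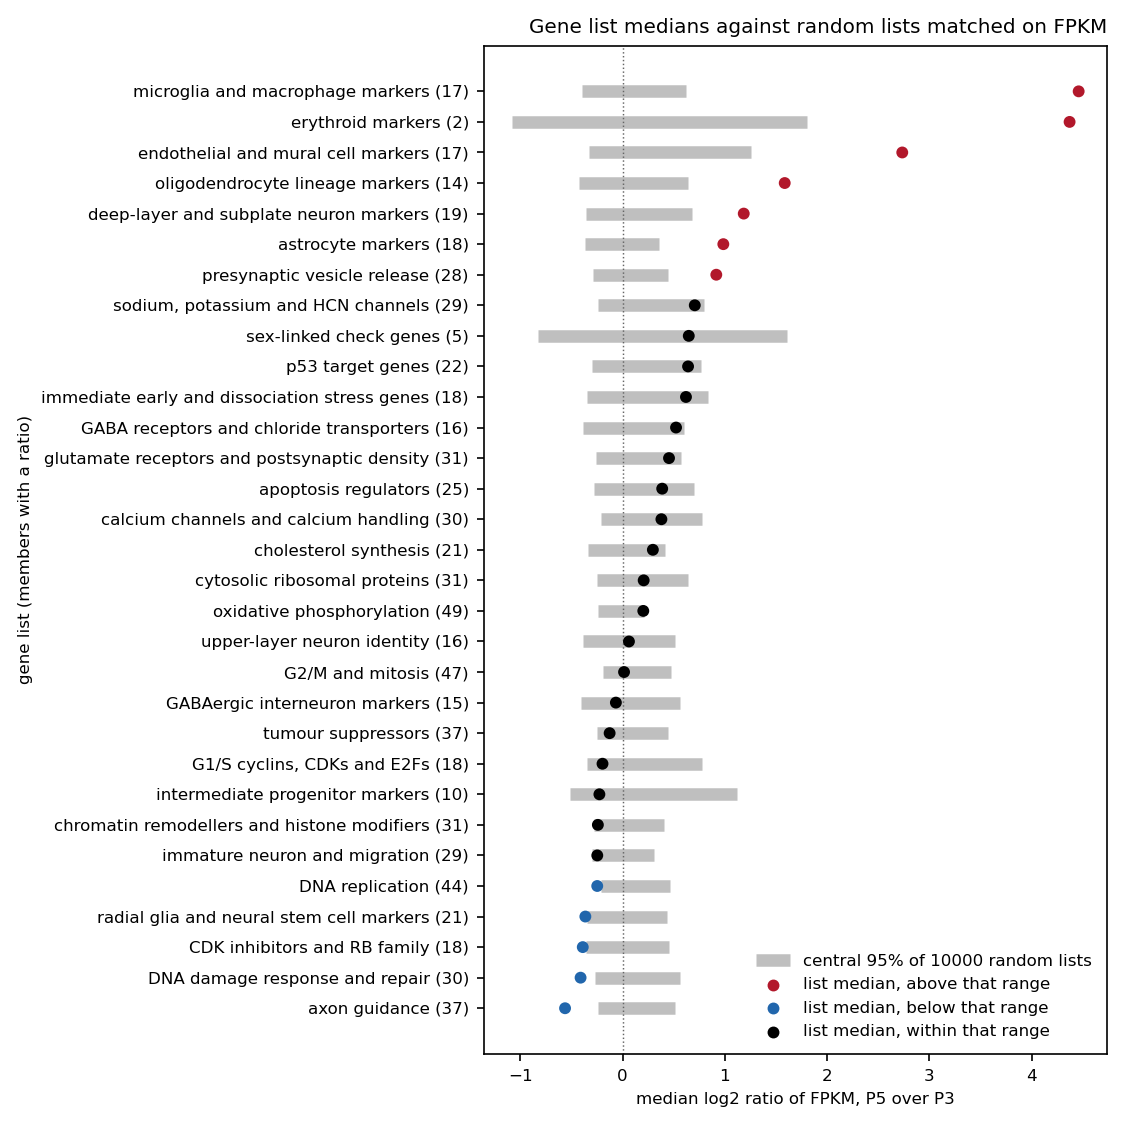
Median log2 ratio of FPKM, P5 over P3, for each of the 31 gene lists (points), with the central 95% of medians of 10000 random lists matched on FPKM (grey bars) and the number of members with a ratio in parentheses. 7 lists lie above that range, led by microglia and macrophage markers at 4.46, 5 lie below it, among them axon guidance at -0.56, and 19 lie within it.

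In all, 0 members of the 31 lists passed the authors' Cuffdiff test, and 0 did when the deposited p-values were adjusted over the list alone, where the lowest q was 0.051, for an erythroid gene. The positions of the lists rest on pooled values, so they describe these libraries and carry no replicate error. Values of Ccnd2, Cux1, Rfc4, Apex1, Ercc1, Lig3, Syt1, Hpca, Nfia, Hbb-b2 and Xist are less certain, because their loci are shared with another row of the table.

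Single genes with the lowest p were chosen after the values were seen, and those at the top of the higher side were near 0 FPKM at P3. The phospholipase gene Pla2g3 (mm9 chromosome 11, 3388230 to 3394169) had 0.012 FPKM at P3 and 8.36 at P5 (p = 0.00036 in the authors' deposited table, the lowest of all), the monocyte receptor gene Cd14 0.020 and 12.2 (p = 0.00056) and the carbonic anhydrase gene Car4 0.030 and 6.53 (p = 0.0038). Genes better detected at P3 included Ctsd, a lysosomal protease, at 18.7 and 96.1 FPKM (log2 ratio 2.36, SE 0.98), Ptgds, a prostaglandin synthase of the meninges and glia, at 10.04 and 176, and the globin row Beta-s at 15.1 and 202. On the lower side, after Uhrf1, the authors' deposited table had Ythdf2, a reader of methylated RNA, at 70.0 and 14.7 FPKM (log2 ratio -2.25, SE 0.86, p = 0.0084). Dnajc21 followed at 26.6 and 3.82 FPKM, then Dcun1d5 at 161 and 39.8 and Fam107b at 37.6 and 9.04. Further down that order, not directly next, was the chromatin remodeller Smarca5 at 242 and 36.9.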

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

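The choice of this result was made after the table was seen. It was picked out because it lies in rows that the comparison does not use: 45 genes had FPKM of at least 1 at either age and yet no test, 34 of them with status FAIL, 2 with HIDATA and 9 with LOWDATA. Several are central to cortical neurons or very abundant. Dcx, which encodes doublecortin of migrating neurons, had 73.0 FPKM at P3 and 51.0 at P5 in the authors' deposited table, and Canx, a chaperone of the endoplasmic reticulum, had 930 and 696, both with status FAIL. Ncan, a proteoglycan of the brain matrix, was at 2157 FPKM at P3 and listed at 0 at P5, and the nuclear RNA Malat1 was listed at 0 at P3 and at 1308 at P5, both with status HIDATA, so no difference is read from either. Of the 34 genes with status FAIL, 29 lay within a factor of 2 between the ages. No explanation was tested.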

How the results depend on the processing

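Dividing the test statistic by its spread, matching on P5 FPKM and leaving out members below 0.1 FPKM at either age were chosen after seeing the data. The counts of genes higher and lower at P5 were 0 and 0 under a minimum FPKM, no filter, centring and removal of markers of other cell types. They were also 0 and 0 under q at 0.01, a log2 ratio of at least 1 and Bonferroni adjustment. With a lowest q of 0.999988 those settings could give nothing else. Neither could centring, which moved each ratio by 0.02 log2 units against a lowest SE of 0.82. With the Cuffdiff statistic divided by its robust spread over genes, which was 0.66, 3 genes were higher at P5 (Pla2g3, Cd14 and Car4, at or below 0.03 FPKM at P3) and 0 lower. Counts of significant list members stayed at 0 in all 124 alternatives tried. The 31 at q of 0.01 and the 31 under centring could give nothing else. Centring moves a list and its random lists alike, so apart from the random draw the 31 centred medians could only keep their side. Of 248 list medians under alternatives, 235 kept their side of the central 95% of random lists, those 31 among them. Among cell cycle and neuronal function lists, G1/S cyclins, CDKs and E2Fs lay outside it at -0.52 with members of at least 1 FPKM at either age, and DNA replication lay inside it at -0.038 as a mean. Immature neuron and migration genes lay outside it at -0.28 as a mean, and at -0.25 with random lists matched on P5 FPKM. Sodium, potassium and HCN channels lay outside it at 0.66 with a pseudocount of 1 FPKM and at 0.71 against lists that were not matched, and GABA receptors and chloride transporters at 0.88 as a mean. The other 6 crossings were in lists of DNA damage, radial glia, oxidative phosphorylation and chromatin genes. Means had the opposite sign to medians for tumour suppressors (0.05), upper-layer identity (-0.06) and interneuron markers (0.22). The cause was not tested. No paired analysis was possible because the values are pooled over the replicates of each age, although the titles share the numbers 1 to 3. Leaving out each replicate, a limma fit and other splits of the samples were not run for the same reason. Of 378 ratios of named genes under alternatives, 7 moved by over 1 SE, all among the 189 with a pseudocount of 1 FPKM. The 189 centred ratios could not, because centring moved each by 0.02 log2 units, against a lowest SE of 0.82. Depth is unknown, and genes of low FPKM carry wide errors (median SE 3.11 log2 units in the lowest decile of FPKM, 0.98 in the highest).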

Other observations

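The symbol families, the comparison of marker lists with interneurons and both tests on DNA replication were chosen only after the results were seen. The same holds for matching random lists on P5 FPKM. Families of genes that share a symbol stem also took different positions. Of 88 stems with at least 12 tested members, 8 lay above the central 95% of matched random lists and 4 below it, against 4.4 outside it by chance if genes were independent. Those below were Sox transcription factors (median log2 ratio -0.74, 10 of 15 lower at P5), Rbm RNA-binding proteins (-0.46, 24 of 33), Zbtb zinc-finger factors (-0.41, 23 of 32) and Zfp zinc-finger proteins (-0.05, 155 of 304). Zfp genes were almost evenly split, with 149 higher at P5, and lay below a random range that was itself above 0 (0.07 to 0.38). In the authors' deposited table Sox11 had 176 FPKM at P3 and 65.1 at P5, Sox21 21.9 and 7.88, Rbm26, at a locus shared with another row, 122 and 43.2, and Zbtb43 14.3 and 5.32, while Sox10 of the oligodendrocyte list had 1.06 and 8.20.

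The 8 higher stems were Slc transporters (median 0.60, 153 of 217 higher at P5), Tmem transmembrane proteins (0.55, 119 of 160), Gpr receptors (1.004, 31 of 37) and Syt synaptotagmins (1.51, 9 of 13), with Atp (0.40), Pex (0.85), Abhd (0.73) and Dusp (0.77). Slc38a3, a glutamine transporter, had 5.34 and 26.7 FPKM in the authors' deposited table, Slc3a2 had 10.1 and 42.9, Gpr37l1, an astrocyte receptor, 0.95 and 24.7, and Syt5 5.32 and 42.0. No gene of these families passed the test.

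Markers of microglia, vessels, oligodendrocytes and astrocytes were higher at P5 in sorts gated on GFP, which would remove such cells unless they were labelled or carried along. Weak detection of low-abundance genes at P3 as the whole cause is argued against, since 4 of the 4 lists stayed above the central 95% of random lists matched on P5 FPKM. A smaller share of the main cell type at P5 would raise every other type alike. Microglia, vessel and interneuron markers did not rise alike in pooled values. Their medians were known when this comparison was set, so it lends no independent support against that cause. Microglia and vessel markers together exceeded those of interneurons by 3.67 log2 units (95% bootstrap interval over genes 1.84 to 4.64). That interval treats genes as independent and carries no replicate error. With a pseudocount of 1 FPKM the list medians were 2.61 for microglia, 1.14 for vessels and -0.09 for interneurons. Interneuron markers, the only comparison, went both ways (7 of 15 higher). More microglia and vascular cells in the P5 sorts remain a candidate explanation: 2 of 2 second marker lists, written before their values were seen, lay above all 10000 random lists (medians 2.42 over 24 genes and 1.79 over 28), although the abundant Rgs5 was at 911 and 905 FPKM and Cspg4 of the second vascular list also marks oligodendrocyte precursors. Neither a difference in age within such cells nor an uneven sort between replicates was tested, and 7 of 20 microglial markers already reached 1 FPKM at P3.

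Genes of low abundance had higher FPKM at P5 more often than at P3, in 70.1% of the lowest decile of mean FPKM (95% exact binomial interval 67.5 to 72.7) against 45.2% of the highest (42.4 to 48.1). Gene length as the cause is argued against, because the share among the lowest 3 deciles was at least 64.8% (61.6 to 67.9) in every quartile of transcript length, with lengths found for 98.5% of them. Fewer detected fragments at P3 may contribute but cannot be told apart from other causes: of 10 genes of receptor, keratin-associated and other families foreign to cortex that were above 0 at a single age, 70% were so at P5 (95% exact interval 34.8 to 93.3), too few to decide. Over all tested genes 466 were listed at 0 at P3 only and 86 at P5 only, and over all rows 8800 were listed at 0 at P3 and 7607 at P5, which goes with that explanation but also with more kinds of cell in the P5 sorts. Intervals cover counting error over genes, which are not independent, and a biological difference with age was not tested.

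DNA replication genes stood apart on the lower side at P5 and mitosis genes did not. The difference of the medians was 0.26 log2 units with a 95% bootstrap interval over genes of -0.28 to 0.68, so the lists were not shown to differ, and whether fewer dividing cells at P5 lie behind the lower replication genes cannot be told apart from other causes on this interval. Fewer radial glia-like cells at P5 cannot be told apart from other causes either: the median of their markers, -0.36 against a random range of -0.35 to 0.43, was known when the test was set and lends no support, and the mean of -0.20 lay within its random range. A change with age within the neurons was not tested.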
